A study of Homo sapiens with 4 samples.

How the data were processed

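Gene expression was measured with 4 Affymetrix whole-transcript arrays, each hybridised with biotin-labelled total RNA. One array each came from LNCaP cells, untransfected LTAD cells, LTAD cells given a control siRNA (siControl) and LTAD cells given an siRNA against PSF (siPSF). PSF is the product of SFPQ. Each array's group was taken from its label, and a group held 1 array. With no replicates, no test across samples was possible, no p-value or error is given, and the number of arrays limits the precision. Per the labels' protocols, LTAD cells were grown in phenol red-free medium with 10% charcoal-stripped serum, and LNCaP cells were kept for 24 h in such medium with 2.5% stripped serum. Array batch, scan date and detection calls were not given in the sources used here.

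The deposited values were log2 probe set levels that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions, settings and which arrays were normalized together were not given in the sources used here. RMA usually puts arrays on a common scale by quantile normalization, but the 4 deposited columns were not on one. The median over all 33297 probe sets was 5.98 for siControl, 6.04 for siPSF, 6.91 for LNCaP and 7.20 for untransfected LTAD. The deposited log2 values therefore shift most genes together wherever a transfected array is set against an untransfected one. Over the genes kept, the median difference was -0.02 for siPSF against siControl, 0.20 for LTAD against LNCaP and -0.92 for siControl against untransfected LTAD.

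Probe sets were named from the platform annotation, and symbols were updated through Entrez gene IDs to the RefSeq gene table of assembly GRCh38.p14, which matched 19429 IDs. Of the probe sets, 19460 had 1 gene symbol and 1754 had several. Another 12083 were unnamed here, and probe sets with several symbols named no gene. For the 769 genes with several probe sets, the one with the highest mean over the 4 arrays was used, which left 18417 genes. A gene was kept if its deposited log2 value reached the median of all gene values, 7.24, in at least 1 array. This kept 11049 genes and left out 7368. No detection call was used. For a gene read under that value in the dimmer array, the log2 difference is therefore a reading against a level not shown to be above background, and no fold is printed. Gene spans in kb came from the same assembly and were known for 99.9% of the kept genes. Some genes are not reported here.

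Each comparison was the log2 difference between 2 arrays, and genes at least 2-fold apart were counted. The groups, comparisons, filter, threshold, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined, and that design used the deposited values. It assumed arrays on a common scale. For siPSF against siControl, whose columns were nearly on one scale, differences are from the deposited values. For LTAD against LNCaP and siControl against untransfected LTAD, counts are given on both scales, and the differences of single genes and lists after quantile normalization of the 4 arrays, which takes out the shift common to most genes. This choice was made after the column medians were seen. Named genes were SFPQ, the 12 highest and 12 lowest kept genes of each of the first 2 comparisons and the 6 highest and 6 lowest of the third, ranked on deposited differences. Small RNA genes, olfactory receptor genes and probe sets with several symbols were left out. From each list the rule added up to 2 members with the largest differences in each direction at 2-fold or more. Further list members are given as examples chosen after their values were seen.

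The 25 gene lists held 566 entries, of which 496 were measured. They covered paraspeckle and DBHS partners, core spliceosome, splicing regulators, androgen-induced and androgen-repressed genes, steroid receptor cofactors, steroid hormone synthesis, G2/M and mitosis, DNA replication, p53 targets, interferon response, unfolded protein and integrated stress response, and homologous recombination and checkpoint. The rest were ribosome biogenesis and MYC, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, prostate non-coding RNAs, reference genes, and markers of neuroendocrine, luminal, basal, mesenchymal and stromal, endothelial or immune cells. A list's median difference was given its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile below 2.5 or above 97.5 counts as outside the central 95%. It describes these arrays and is not a test of the conditions, since genes are not replicates. The prostate non-coding RNA list had 1 kept member, MALAT1, and got no percentile.

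The computation was tested on simulated data for siPSF against siControl with 11049 genes. All 50 genes planted at 3-fold were recovered, 50 of 50 at 4-fold and 25 of 50 at exactly 2-fold, and 0 of 10835 unchanged genes were called. The simulated noise was independent and alike for all genes, with a standard deviation of 0.219 log2 taken from the siPSF and siControl arrays. With that setting a 2-fold call of an unchanged gene was all but excluded beforehand, so the 0 is no false-call rate for these arrays. In 200 simulated pairs with no effect of gene span, the longest genes (those over 85.4 kb) lay outside the central 95% in 8. The alternatives were no filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, quantile normalization, median or loess centring (span 0.3), the mean of a gene's probe sets, random lists without matching, and other arrays as the control or as the LTAD array. Added after the data were seen were quantile normalization with a filter on its own values or with other arrays, and classes of gene span. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.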

Results

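The study profiled LNCaP, an androgen-responsive human prostate cancer line, and LTAD, a subline obtained from it by prolonged growth without androgen and a model of castration-resistant disease. PSF, encoded by SFPQ, is an RNA-binding protein of the DBHS family that takes part in transcription and splicing. There was 1 array each for LNCaP, untransfected LTAD, siControl LTAD and siPSF LTAD, each reading 33297 probe sets, and no group had a replicate. Differences below are therefore between single arrays.

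SFPQ, the siRNA target, was lower in the siPSF array than in the siControl array. Its deposited log2 level was 9.46 with siPSF and 10.91 with siControl, a 2.72-fold lower level (log2 difference -1.44). In untransfected LTAD and in LNCaP the SFPQ level was 11.25 and 11.12, and after quantile normalization the 2 lines differed by -0.02. Against untransfected LTAD, also after quantile normalization, SFPQ was lower with siPSF by less than 2-fold (-0.95). NONO, the DBHS partner of PSF, differed by 0.07 between siPSF and siControl. PSPC1, another DBHS protein and a paraspeckle component, was 2.22-fold higher with siPSF, at 10.12 against 8.97.

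**Figure D1:**
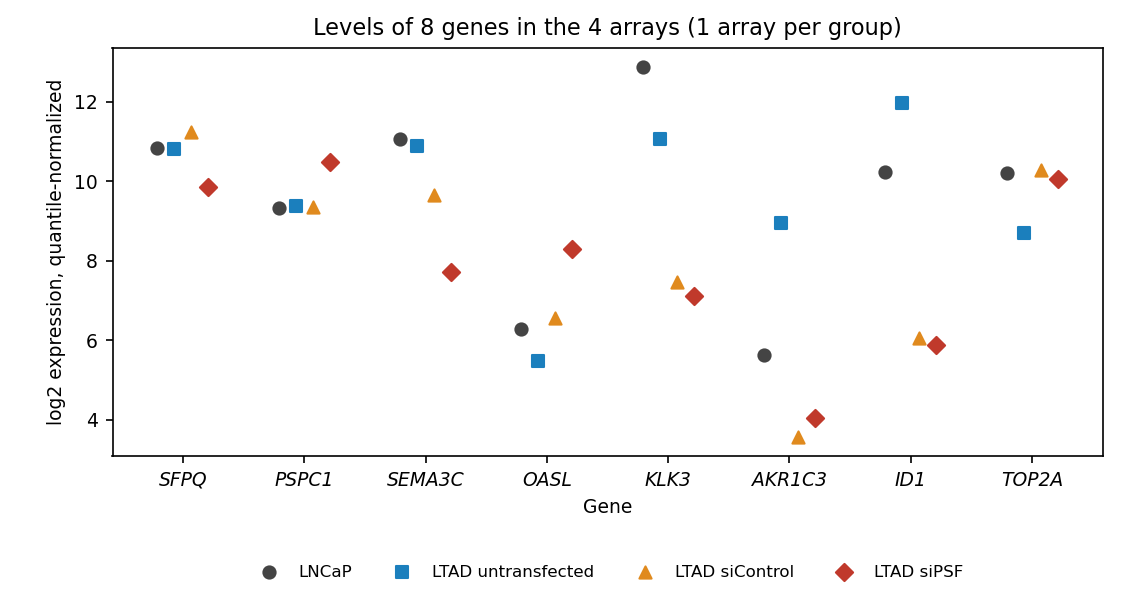
Log2 expression of 8 genes after quantile normalization (vertical axis), with 1 point per array and the 4 arrays as symbols. SFPQ was 9.87 with siPSF against 11.23 with siControl, and KLK3, AKR1C3 and ID1 were lower in both transfected arrays than in untransfected LTAD and LNCaP.

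The first comparison asked what loss of PSF does to gene expression in the castration-resistant model. Interferon-induced genes and p53 target genes were higher with siPSF than with siControl, and genes of cholesterol synthesis, the unfolded protein response, DNA replication, mitosis and ribosome biogenesis were lower. Against untransfected LTAD in place of siControl, these lower groups turned to the high side of random lists. Most differences were small, with 8 genes at least 2-fold higher and 81 at least 2-fold lower among 11049 kept genes. OASL and IFIT1, antiviral genes induced by interferon, read 7.84 against 6.03 and 8.04 against 6.65. Both passed the filter only through the siPSF array. SEMA3C, a secreted semaphorin, was lowest at 4.01-fold. After quantile normalization it read 7.73 with siPSF, 9.65 in siControl and 10.88 in untransfected LTAD.

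AGT, the precursor of angiotensin, was higher by 1.40 with siPSF and, like OASL and IFIT1, passed the filter only through the siPSF array. JUN, a subunit of the AP-1 transcription factor, was 2.25-fold higher. SLC44A4, a choline transporter-like protein, was higher by 1.06 and the kinesin gene KIF27 was just at the 2-fold threshold, and below it after quantile normalization at 0.95. LRRFIP1 was higher by 1.18 in the probe set used, but its 10 probe sets disagreed and ran from -0.60 to 2.30. The next highest genes stayed under 2-fold, with PLEKHH1 at 0.97, ANP32A-IT1 at 0.95, MYLIP, a ubiquitin ligase that targets the LDL receptor, at 0.93, and UBE2Q2P1 at 0.92.

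Among the 12 lowest genes, NLGN1, a synaptic adhesion protein, was lower with a log2 difference of -1.64, TENM2, a teneurin, with -1.58, GABRA3, a GABA receptor subunit, with -1.39, and ANK3, the membrane adaptor ankyrin-G, with -1.59. PRKCA, protein kinase C alpha, differed by -1.65. GNAQ, a G protein subunit, differed by -1.49, with its second probe set at -0.89. NAALADL2 differed by -1.87, CMSS1 by -1.67, ACTR3C by -1.46 and SUPT3H by -1.42. After quantile normalization NAALADL2 and ANK3 were also lower in siControl than in untransfected LTAD, at 8.35 against 10.12 and 10.22 against 11.15. CMSS1 was higher in siControl, at 10.59 against 9.89. The rest of the 12, besides SEMA3C, lay closer between these 2 arrays. SERPINI1, the gene of neuroserpin and the lowest of the androgen-repressed list, differed by -1.18. In 8 of the 12 highest and 6 of the 12 lowest genes the dimmer array read under the filter value of 7.24, and in 1 and 2 of them both arrays did, so with no detection call their differences are readings not shown to be above background. Of the 81 genes at least 2-fold lower, 73 (90.1%) were among the 2208 longest genes, those with a genomic span over 85.4 kb. Their median span was 303 kb, against 27.6 kb over all kept genes.

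**Figure D2:**
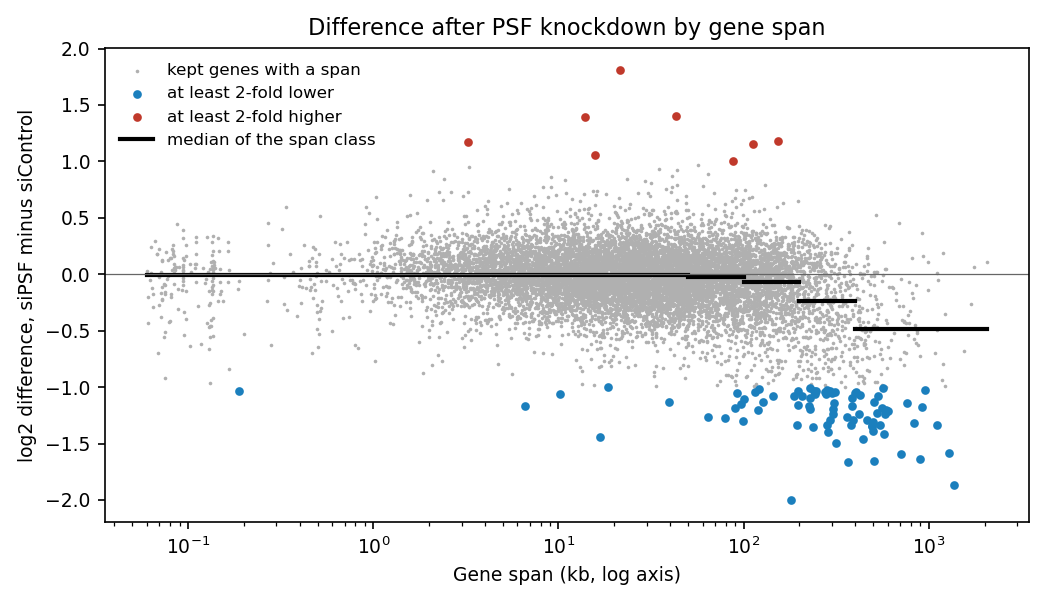
Log2 difference of siPSF minus siControl (vertical axis) against gene span in kb (log axis) for the kept genes, with genes at least 2-fold apart in colour and black lines for the median of each span class. The median was -0.48 for 190 genes over 400 kb and -0.23 for 475 genes of 200 to 400 kb, with 7470 genes up to 50 kb close to 0.

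Of the 24 lists that could be scored, 14 had a median outside the central 95% of matched random lists, where 1.2 would be outside by chance if lists were independent. On either scale 11 were outside for LTAD against LNCaP, and 9 for siControl against untransfected LTAD, with no siRNA against PSF. A count above 1.2 was thus not particular to the knockdown. The interferon list had a median of 0.29 (percentile 100), with 13 of 14 kept members above 0. Among them were IRF9 at 0.63, HERC6 at 0.61 and ISG15 at 0.49. The filter left out the rest of its 30 measured genes. OASL and IFIT1 reached the filter value only in the siPSF array, so their place among the kept members rests on that array. IRF9 and HERC6 read under the filter value in siControl. ISG15, ISG20, IRF7, IFIT5, OAS1 and OAS3 did so in both arrays, at levels not shown to be above background. The p53 target list had a median of 0.24 (percentile 100), and 18 of its 20 members were above 0. CDKN1A, the p21 cell-cycle inhibitor, was higher by 0.83, TP53I3 by 0.69 and SESN2 by 0.57, each under 2-fold. Paraspeckle and DBHS partners had a median of 0.13 (percentile 99.6), with MALAT1 at 0.32 and CPSF6 at 0.30 besides PSPC1, but came to 93.7 against untransfected LTAD after quantile normalization. Luminal epithelial markers had a median of 0.13 (percentile 99.4), with CD24 at 0.50 and ELF3 at 0.39. Hypoxia and glycolysis genes had a median of 0.10 (percentile 99.1), which came to 97.3 after quantile normalization.

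Cholesterol synthesis genes had the lowest list median, -0.42 (percentile 0.010), and 13 of 14 members were below 0. MSMO1 differed by -0.98, SQLE, squalene epoxidase, by -0.82 and HMGCS1 by -0.81. The unfolded protein and integrated stress response list had a median of -0.31, with SDF2L1 at -0.55 and HSPA5, the chaperone BiP, at -0.31. DNA replication genes had a median of -0.29, with CDC6 at -0.65 and MCM6 at -0.60. All 20 kept genes of ribosome biogenesis and MYC were below 0, with a median of -0.25. The G2/M and mitosis list had 27 of 29 members below 0, with a median of -0.21 and KIF11 at -0.76. Homologous recombination and checkpoint genes had a median of -0.23 (percentile 0.24, but 5.81 with the 75th percentile filter) and oxidative phosphorylation genes -0.15 (percentile 0.77). The 5 kept androgen-repressed genes had a median of -0.36 (percentile 0.70), but MET, SERPINI1, UGT2B17 and CCN3 read under the filter value of 7.24 in both arrays, and with quantile normalization and its own filter the list came to percentile 68.5. Fatty acid synthesis genes had a median of -0.20, with a percentile of 2.12 that became 3.39 after quantile normalization. With untransfected LTAD as the control, percentiles turned to 100 for G2/M and for DNA replication, 99.9 for homologous recombination, 99.7 for the stress response, 98.5 for ribosome biogenesis, 94.1 for cholesterol synthesis and 92.7 for fatty acid synthesis. Oxidative phosphorylation came to 57.2, or 42.3 after quantile normalization, and luminal markers to 48.4, inside the random range. The calls of these 9 lists thus depended on which LTAD array served as control.

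Splicing genes stayed near their matched random lists, at percentile 16.4 for the core spliceosome and 25.2 for hnRNP, SR and other splicing regulators, where MBNL1 was lowest at -0.84. Androgen-induced genes were at percentile 76.0 and steroid receptor cofactors at 78.7. Reference genes were at 51.1. Steroid hormone synthesis was at 9.0, neuroendocrine markers at 57.9, basal markers at 89.0, mesenchymal markers at 83.7, and stromal, endothelial and immune markers at 49.9. Each of the lists in the last sentence had only 4 kept members, too few to show that its genes did not shift. Among all lists inside the central 95%, androgen-induced genes lay outside it in 4 alternatives (down to 0.71), neuroendocrine markers in 2 (up to 98.7) and steroid hormone synthesis in 1 (0.20). Interferon genes and p53 targets stayed above the central 95% in all 11 and all 12 of their alternatives.

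**Figure D3:**
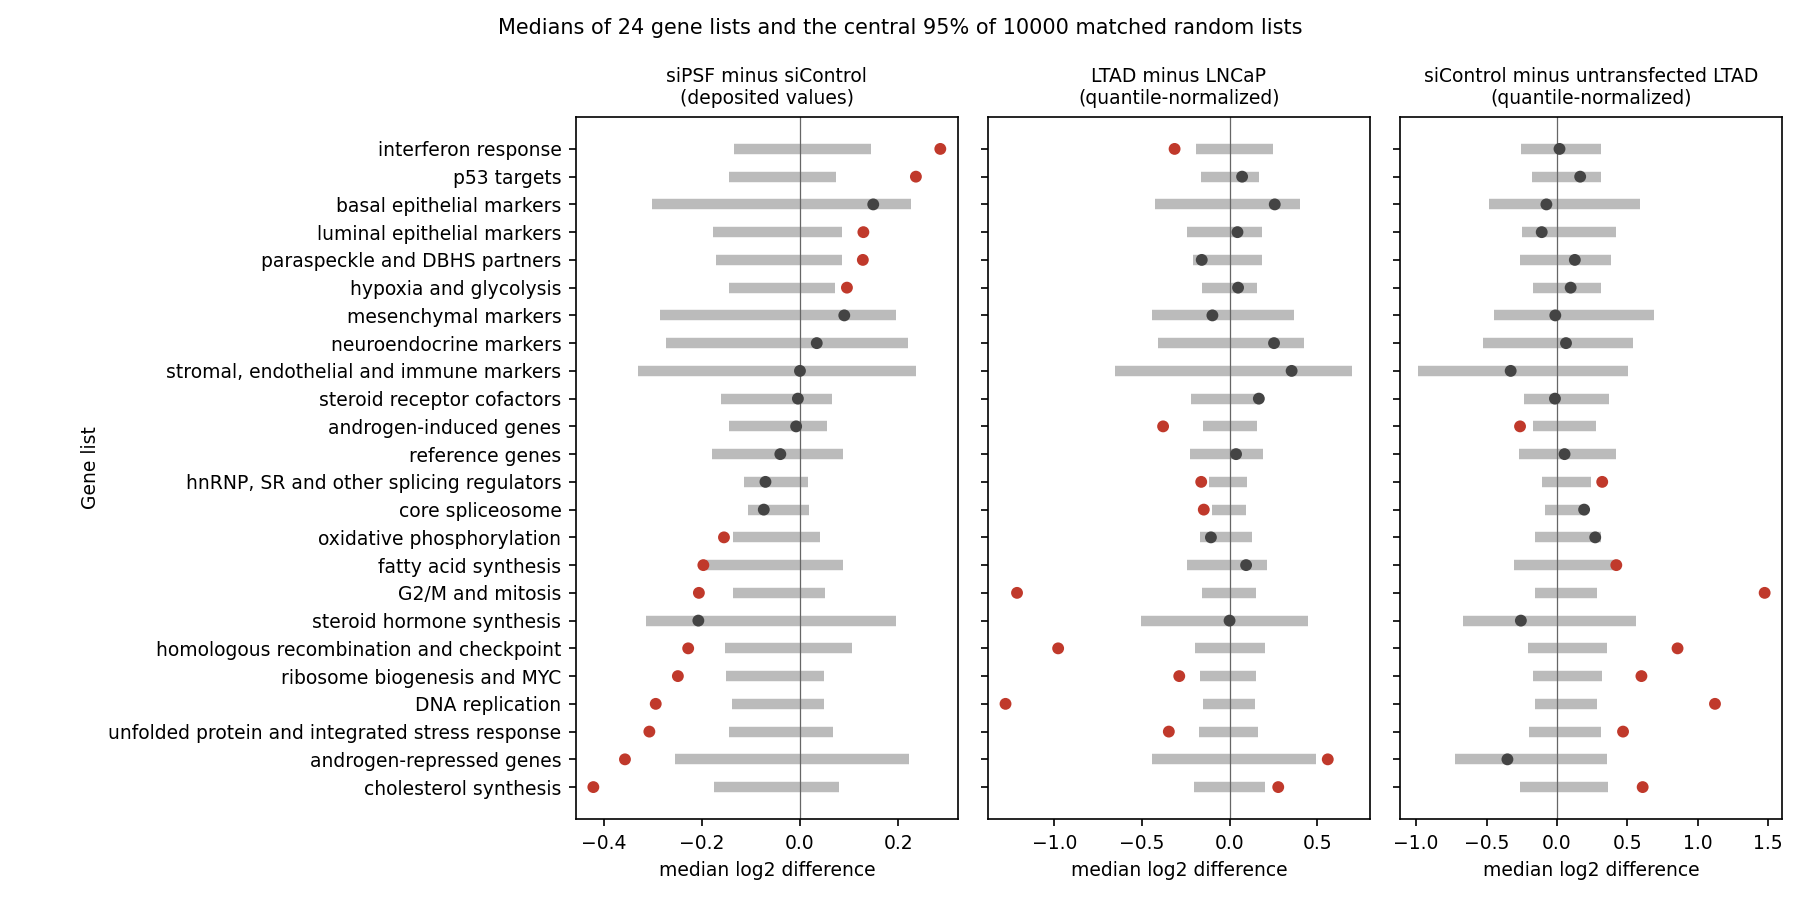
Median log2 difference of 24 gene lists (horizontal axis) in the 3 comparisons, as points, from deposited values for siPSF against siControl and after quantile normalization for the others, with grey bars for the central 95% of 10000 matched random lists and red points outside it. Cholesterol synthesis was lowest with siPSF at -0.42, and G2/M genes were at -1.21 in LTAD against LNCaP and at 1.48 in siControl against untransfected LTAD; the first reached percentile 66.5 with siControl LTAD in place of untransfected LTAD.

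The comparison of LTAD with LNCaP asked how the androgen-deprived subline differs from its parent. The LNCaP cells had themselves been kept for 24 h in stripped-serum medium, at 2.5% serum against 10% for LTAD. Effects of line and of culture therefore cannot be told apart here. Untransfected LTAD had lower levels of androgen-induced genes and of G2/M and DNA replication genes and higher levels of cholesterol synthesis genes, and the G2/M and DNA replication medians lay inside the random range when siControl LTAD took its place. After quantile normalization 251 genes were at least 2-fold higher and 378 at least 2-fold lower, so that 39.9% of these genes were higher. Of these, 54 and 100 were also at least 2-fold apart from LNCaP in the same direction in siControl LTAD, so most were not seen at 2-fold in the second LTAD array. Independent lists would share 5.68 and 11.2, and the LNCaP array common to both differences raises such counts by an amount that single arrays do not give. On the deposited values the counts were 355 and 255, with 58.2% higher. PLPPR1 read 11.08 in LTAD against 5.03 in LNCaP, and PIGR, the polymeric immunoglobulin receptor, 5.18 against 10.47. For all 12 highest and 10 of the 12 lowest genes the dimmer array was under the filter value of 7.24 on the deposited scale, so the size of these differences is a reading against a level not shown to be above background.

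ROBO2, an axon guidance receptor, was higher by 5.32 on the log2 scale, and the cadherin family genes PCDH19, CDH12 and FAT4 by 4.86, 4.21 and 3.98. LUM and CCDC80, which encode extracellular matrix proteins, were higher by 5.02 and 5.29. ANXA1, annexin A1, was higher by 4.64, the serotonin receptor gene HTR7 by 4.62, ADGRL3 by 4.40, PKIA, an inhibitor of protein kinase A, by 4.38, and the transcription factor gene DACH1 by 4.12. In siControl LTAD, LUM and CCDC80 read 3.21 and 5.60, under their LNCaP levels of 3.78 and 5.74, and ROBO2, PKIA and HTR7 read 5.18, 5.39 and 5.81, close to 4.96, 4.87 and 5.23 in LNCaP. PLPPR1 read 6.16 against 5.03, PCDH19 6.87 against 4.28, ADGRL3 6.37 against 4.03, CDH12 6.29 against 4.26, DACH1 5.86 against 4.33, FAT4 5.42 against 4.33 and ANXA1 7.06 against 5.88. Other stromal markers were close in the 2 lines, with COL1A1 at 0.28 and COL3A1 at 0.43.

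LCN2, lipocalin 2, read 5.82 in LTAD against 11.07 in LNCaP, and the chemokine gene CCL20 differed by -4.76. PLA2G4A, a cytosolic phospholipase A2, differed by -3.93, the desmosomal cadherin gene DSC3 by -3.73, COLCA1 by -3.40, CP, ceruloplasmin, by -3.39, ASPH by -3.38 and the protease gene MMP7 by -3.18. MAGEC2, a cancer-testis antigen, differed by -3.15, and TNFSF10, the death ligand TRAIL, by -3.03. Of 2 related aldo-keto reductases of steroid metabolism, AKR1C2 was lower with a difference of -3.14 and AKR1C3 higher by 3.31. Each of the 12 lowest genes, PIGR and AKR1C2 among them, was also at least 2-fold below LNCaP in siControl LTAD after quantile normalization. There LCN2 read 6.20 against 11.07, PLA2G4A 3.96 against 7.89, TNFSF10 4.66 against 7.33 and ASPH 8.19 against 10.69. The LNCaP array is common to both differences. On the deposited values all but ASPH read under the filter value in siControl, at levels not shown to be above background.

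Androgen-induced genes had a median of -0.38 in LTAD against LNCaP, below all 10000 random lists (percentile 0), with 17 of 26 members below 0 and 7 at least 2-fold lower. KLK3, the gene of prostate-specific antigen, was 3.55-fold lower and ABCC4 3.47-fold lower. Among androgen-repressed genes (median 0.56, percentile 98.4), MET, the hepatocyte growth factor receptor, read 6.60 against 5.18. That list's call was lost with no filter (percentile 81.0), with quantile normalization and its own filter (92.4), and on deposited values with siControl LTAD in place of untransfected LTAD (97.3). All 28 DNA replication genes and all 29 G2/M genes were below 0, with medians of -1.28 and -1.21 and differences of -1.95 for CDC6 and MELK, -1.89 for MCM10 and -1.87 for KIF11. Homologous recombination and checkpoint genes had a median of -0.98, with BRIP1 at -2.40 and BRCA1 at -2.38, against LTAD levels under the filter value. Cholesterol synthesis genes were higher, with a median of 0.28 (percentile 99.7), STARD4 at 1.83 and LSS at 1.03.

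Lists with smaller negative medians were the stress response (-0.35), the interferon response (-0.31, with OAS3 at -1.41), ribosome biogenesis (-0.29), splicing regulators (-0.16) and the core spliceosome (-0.15, and 0.02 on the deposited values, where the median of all kept genes was 0.20). In other lists, ENO2, a neuroendocrine marker, was higher by 1.28 and the mesenchymal gene TWIST1 by 1.33, and GDF15 differed by -1.28. The lists of these genes lay inside the random range. Neuroendocrine markers were at percentile 87.4 and mesenchymal markers at 29.0, with 4 kept members each, and p53 targets at 79.5. Neuroendocrine markers lay above that range in 5 alternatives (up to 99.8) and p53 targets in 4 (up to 99.5). The rule also named CD24, SREBF1 and SCD, which were under 2-fold after quantile normalization at 0.96, 0.92 and 0.92. With siControl LTAD in place of untransfected LTAD and quantile normalization, the androgen-induced list was again at percentile 0 and cholesterol synthesis at 100. Percentiles moved to 66.5 for G2/M, 35.2 for DNA replication, 4.49 for homologous recombination, 98.3 for ribosome biogenesis, 87.1 for the core spliceosome, 75.8 for the stress response, 40.8 for splicing regulators and 2.59 for interferon genes, and CDC6, MCM10 and GDF15 turned to 0.61, 0.27 and 0.62 and AKR1C3 to -2.08.

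SiControl LTAD was set against untransfected LTAD to see how far 2 arrays of the same line lie apart. The siControl array had higher levels of mitotic, replication, ribosome biogenesis and cholesterol synthesis genes and much lower levels of single genes such as ID1, AKR1C3 and KLK3. After quantile normalization 612 genes were at least 2-fold higher and 477 at least 2-fold lower. The deposited counts were 65 and 4791. These 1089 genes exceed the 629 between LTAD and LNCaP and the 80 between siPSF and siControl on the same scale.

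ID1, an inhibitor of basic helix-loop-helix factors, read 6.06 in siControl LTAD against 11.96 in untransfected LTAD, and REG4, DENND1B, LUM, CCDC80 and ADAMTS1 differed by -5.72, -5.64, -5.59, -5.43 and -5.37. KLK3 read 7.47 against 11.06 and AKR1C3 3.56 against 8.95. The dimmer array was under the filter value for all 6 lowest and 5 of the 6 highest genes. BNC2 was higher by 5.24, ZNF729 by 4.52, the histone gene H3C11 by 3.55, PEG10, an imprinted retrotransposon-derived gene, by 3.48, PRSS1 by 3.45 and FSD1 by 3.39. G2/M genes had a median of 1.48 and DNA replication genes of 1.12, with every kept member above 0, and HMMR, CDC6 and RFC4 were higher by 2.17, 2.56 and 2.33. Homologous recombination genes had a median of 0.86, cholesterol synthesis of 0.61, ribosome biogenesis of 0.60, the stress response of 0.47 (ASNS 2.19) and splicing regulators of 0.32. Fatty acid synthesis had a median of 0.42 at percentile 97.6, and its call was lost with loess centring (97.0) and with quantile normalization and its own filter (97.2). Androgen-induced genes had a median of -0.26 (percentile 0.28), with HERC3 at -2.13 besides KLK3, but the call was lost on deposited values with no filter (2.82), with the 75th percentile filter (9.15) and without matching (5.09). SNRPG was higher by 2.13, but its 2 probe sets differed in size. On the deposited values, where the median of all kept genes was -0.92, they were at -0.38 and 1.28.

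Genes that differed between LTAD and LNCaP were then set against those that differed with siPSF, with no array shared by these differences. After quantile normalization 11 genes were at least 2-fold higher in LTAD than in LNCaP and at least 2-fold lower with siPSF, where independent lists of these sizes would share 1.66 and draws matched on gene span and expression shared 6.73 (central 95% from 3 to 11). They were ANXA1, ARHGAP6, CDH12, DIAPH2, DSEL, GABRA3, LUZP2, NLGN1, TENM2, TSPAN7 and ZFHX4. ANXA1 (6.55 and 5.55) and CDH12 (5.73 and 4.40) read under the filter value in siControl and in siPSF. On the deposited values 14 genes were shared, against 2.60 for independent lists and 9.0 in the matched draws (central 95% from 4 to 14). Genes lower in both numbered 6 on the deposited values against 1.87, and 8 after quantile normalization against 2.50, and 1 gene, SLC44A4, was lower in LTAD and higher with siPSF. Over all kept genes the 2 differences had a Pearson correlation of 0.07 across genes, which are not independent replicates.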

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

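Tests with quantile normalization combined with another array or with a filter on its own values, and with classes of gene span, were chosen after the data were seen; the other alternatives were planned. Single arrays give no spread, so a count here moved when it changed by over 1.5 times. The SFPQ level kept its direction in each alternative, from -1.78 against untransfected LTAD to -0.95 against the same array after quantile normalization, where it was under 2-fold. The longest genes (over 85.4 kb) had a median below 0 in each one, from -0.05 to -1.13. Signal over background limits dim genes, and no detection call was used. Unless the construction is named, the cause was not tested.

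For siPSF against siControl, with 8 higher and 81 lower genes, no filter gave 19 higher and the 75th percentile filter 4 and 51. Thresholds, which change the counts by construction, gave 89 and 380 at 1.5-fold and 1 and 6 at 3-fold. Untransfected LTAD as control gave 49 and 4989 because of the array scale, with the longest genes at -1.13, and 511 and 579 after quantile normalization. The mean of both LTAD controls gave 888 lower, and 55 and 259 after quantile normalization. The number of lists outside the central 95% was 14 and became 9 with that mean, 9 with it after quantile normalization and 9 with untransfected LTAD after quantile normalization.

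For LTAD against LNCaP, with 355 higher and 255 lower genes, no filter gave 598 higher and the 75th percentile filter 213 and 154. The thresholds gave 1425 and 559 at 1.5-fold and 119 and 81 at 3-fold. Higher genes numbered 235 with median centring, 212 with loess centring and 223 with quantile normalization and its own filter. SiControl LTAD in place of untransfected gave 52 and 2719, and the mean of both LTAD arrays 90 and 415, or 144 higher after quantile normalization. For siControl against untransfected LTAD, with 65 and 4791, no filter gave 9480 lower, the 75th percentile filter 2506 lower, 1.5-fold 170 and 8144, and 3-fold 19 and 1262. Scaling gave 612 and 477 with quantile normalization, 641 and 441 with its own filter, 557 and 555 with median centring and 540 and 508 with loess centring.

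Genes higher in LTAD and lower with siPSF numbered 14. They were 9 with the 75th percentile filter, 86 at 1.5-fold and 1 at 3-fold. With siControl LTAD in place of untransfected they were 6, and with the mean of both LTAD arrays 8, where the siControl array enters both differences. With untransfected LTAD as control, which shares its array with the other difference, they were 327, or 168 after quantile normalization, and with the mean control 211, or 104.

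Reversals came almost entirely with a change of array. With untransfected LTAD as control for siPSF, list percentiles were 100 for G2/M, 100 for DNA replication, 99.7 for the stress response, 48.4 for luminal markers, 99.9 for homologous recombination, 98.5 for ribosome biogenesis, 94.1 for cholesterol synthesis, 92.7 for fatty acid synthesis and 57.2 for oxidative phosphorylation. After quantile normalization the same control gave 100, 100, 99.5, 33.3, 99.9, 99.6, 88.9 and 81.2 for the first 8 of these, and 42.3 for oxidative phosphorylation, which did not turn there. With the mean control the G2/M, DNA replication, stress response, homologous recombination and ribosome biogenesis lists were at 100, 100, 81.3, 74.8 and 78.7, and after quantile normalization at 100, 100, 91.5, 86.5 and 88.2. LRRFIP1, JUN and SLC44A4 were at -0.63, -0.10 and -1.17 against untransfected LTAD. SLC44A4 was at -0.22 there after quantile normalization and at -0.0574 with the mean control. Androgen-repressed genes came to percentile 68.5 with quantile normalization and its own filter.

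With siControl LTAD set against LNCaP, the core spliceosome, G2/M, stress response and ribosome biogenesis lists were at 75.6, 76.8, 81.2 and 96.6, and after quantile normalization at 87.1, 66.5, 75.8 and 98.3. On deposited values single genes turned to -0.78 for ROBO2, -1.12 for CCDC80, -1.18 for LUM, -0.40 for HTR7, -0.47 for PKIA, -2.88 for AKR1C3, -0.12 for STARD4, -0.44 for MET, -0.19 for TWIST1, -0.0652 for ENO2, -0.68 for CD24, -0.46 for SREBF1 and 0.12 for GDF15. After quantile normalization CCDC80, LUM, AKR1C3, GDF15, MCM10 and CDC6 were at -0.14, -0.57, -2.08, 0.62, 0.27 and 0.61. INSM1 in siControl against untransfected LTAD was at 0.0102 after quantile normalization and at 0.0102 with its own filter.

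Over all alternatives, list percentiles kept their label in 230 results for siPSF against siControl, with 18 weaker, 7 stronger and 28 reversed. For LTAD against LNCaP the numbers were 244, 20, 11 and 8, and for siControl against untransfected LTAD 178, 5, 4 and 0. Single genes kept their difference within 1.5-fold in 215, 359 and 184 results, moved by more in 44, 106 and 241 and reversed in 5, 19 and 2. The large number moved for siControl against untransfected LTAD follows from taking out the array scale.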

Other observations

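The tests of array scale, exchanged labels and batch for the siControl array, and the classes of gene span, were chosen after the result was seen, while the comparison with LNCaP and the draws matched on span were added to the design before their own results were computed. Several gene groups were at opposite ends in the 3 comparisons after quantile normalization. TOP2A was 8.71 in untransfected LTAD, 10.22 in LNCaP, 10.29 in siControl LTAD and 10.06 with siPSF, and MKI67 differed by -1.37 between LTAD and LNCaP and by 1.45 between siControl and untransfected LTAD. Cell-cycle genes were thus low in the untransfected LTAD array and near the LNCaP level in both transfected arrays. KLK3 was also lower in untransfected LTAD than in LNCaP but lowest in the transfected arrays. It read 12.89 in LNCaP, 11.06 in untransfected LTAD, 7.47 in siControl LTAD and 7.11 with siPSF. VIM, a mesenchymal filament gene, was higher in siControl than in untransfected LTAD by 1.88, but FN1 and TWIST1 of the same list differed by -1.01 and -0.68. The mesenchymal list had a median of -0.01 there (percentile 35.6, from 4 kept members).

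Genes at least 2-fold lower with siPSF were mostly long. Of 190 genes over 400 kb, 162 (85.3%) were below 0 and 15.8% at least 2-fold lower, against 0.080% of 7470 genes up to 50 kb. In siControl against untransfected LTAD, with no siRNA against PSF, the shares at least 2-fold lower were 21.1% and 3.41% after quantile normalization. Of the genes higher in LTAD than in LNCaP after quantile normalization, 123 of 251 (49.0%) were among the 2208 longest genes (over 85.4 kb), as were 94 of 378 lower genes (24.9%).

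A first hypothesis is that loss of PSF lowers long genes. The longest genes had a median difference of -0.10 with siPSF, below all 10000 random lists matched on expression (central 95% from -0.03 to -0.01). In pairs without PSF siRNA the longest genes were outside the random range as well, after quantile normalization. Their percentile was 0 for siControl minus untransfected LTAD and for siControl minus LNCaP, and 100 for untransfected LTAD minus LNCaP. The percentile alone therefore does not single out loss of PSF. A siControl array that read long genes too high would leave siPSF level with LNCaP in them, if transfection and culture left long genes unchanged. Instead siPSF minus LNCaP had a median of -0.10 in the longest genes after quantile normalization, against 0.06 in the others, while siControl minus LNCaP had 0.01 and 0.06. A fall of long genes shared by both transfected arrays could hide a high siControl reading, so these values cannot exclude that explanation. Also open is a share of transfection or culture. After quantile normalization, siControl minus untransfected LTAD was -0.05 in the longest genes and 0.06 in the others. SiPSF minus siControl was -0.09 and -0.00. Over 400 kb the medians were -0.19 in the former and -0.47 in the latter. The longest genes held 171 of the 477 genes at least 2-fold lower in the former and 66 of 73 in the latter.

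The overlap of genes higher in LTAD and lower with siPSF may follow from gene span. The 11 genes shared after quantile normalization were compared with 10000 draws of as many genes matched on span and expression, which shared 6.73 on average and 3 to 11 in their central 95%. The overlap was thus at the upper end of what these draws gave. They matched span in 20 classes, so span was held only roughly among the longest genes. There the share at least 2-fold lower with siPSF still rose, from 5.89% at 200 to 400 kb to 15.8% over 400 kb. The draws therefore do not settle how large an overlap span alone gives. Genes lower in LTAD and lower with siPSF numbered 8, above the 1 to 7 of their draws (percentile 98.8), so the excess was not particular to genes higher in LTAD. On the deposited values these were 6 against 0 to 6.

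SiControl LTAD lay nearer to LNCaP than to untransfected LTAD. Array scale alone cannot account for this, since 1089 genes were still at least 2-fold apart between siControl and untransfected LTAD after quantile normalization, against 578 between siControl and LNCaP. An exchange of the labels of LNCaP and untransfected LTAD cannot be told apart from other causes here, since 70.3% of the 629 genes apart between these were nearer to LNCaP in siControl, which restates the pattern. Androgen-induced genes were lower than in LNCaP in untransfected LTAD (median -0.38) and in siControl LTAD (-0.59), which does not settle it. A batch of culture or hybridization shared by the transfected pair, which were only 80 genes apart, cannot be told apart from transfection, since no label gives a batch.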
